A study of Arabidopsis thaliana with 2 samples.

How the data were processed

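RNA was extracted from Arabidopsis thaliana embryos of the Col-0 ecotype between the globular and the heart stage, which were dissected out of siliques of wild-type plants and of a mutant called lefko. The labels give 1 sample per genotype. The mutant sample itself is labelled lefko1, whereas the series title, the extraction protocol and the headings of the tables speak of lefko2. Both names were taken to mean the only mutant sample of the series, called here the lefko mutant. No label names the mutated gene, so its own reads were not analysed here. Libraries were made with a low-input TruSeq kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. HISAT2 2.0.4 and the TAIR10 genome are named in the submitters' processing notes. The program that called splicing events and its test are not given in the sources used here.

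The authors deposited 4 tables of splicing events, for alternative 5′ splice sites, alternative 3′ splice sites, intron retention and exon skipping. Each row gives a gene, the coordinates of 3 exons, read counts for both genotypes, a p-value and a false discovery rate (FDR), the last 2 as the authors' caller gave them. The largest FDR listed was 0.0500, so the tables hold only the events that passed the authors' threshold. The count columns that the authors deposited join 3 whole numbers in each cell, in columns headed IC and SC. These headings were read as reads that include the alternative segment and reads that skip it. No label says whether the 3 numbers are cultures, libraries or sequencing runs. They were therefore summed and each genotype was counted as 1 sample, and a share is that of the summed reads. A range over the 3 values is given for some events only, and the genotypes were called separated where all 3 values of one lay above or below those of the other. The fixed plan foresaw 1 library per genotype and read counts of single libraries. Joined counts fit no count model, and no model of replicates was run.

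The inclusion share was computed as inclusion reads over inclusion and skipping reads. It was not corrected for the length that reads can fall on, so a share is comparable between genotypes for one event and not between events. Exact Clopper-Pearson intervals at 95% cover counting error only. Where a share was 0, the limit given is 3 reads of the total and not the end of that interval. The log2 odds ratio, with a pseudocount of 0.5 reads, does not depend on that length. Fisher's exact test on the summed reads (two-sided) compares the 2 samples and not the 2 genotypes. Reads were without molecular identifiers as far as the labels say, so they are not independent molecules. The median event was covered by 91 wild-type reads and by 43.5 mutant reads. Library totals were not analysed here. The number of events the authors tested was recovered from their p-values and FDRs, because an FDR of the Benjamini-Hochberg kind times rank over p gives that number. It came out within 1% of one value in 61 of the 70 alternative 5′ events, 53 of 66 alternative 3′ events, 106 of 115 retention events and 14 of 19 skipping events, and p-values written as 0 gave none.

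Coordinates are those of the authors' tables, whose chromosome accessions equal those of the TAIR10.1 RefSeq assembly used here for sequence and annotation. Starts were counted from 0 in the tables and are printed here counted from 1: with that reading 583 of the 810 listed exons equalled an annotated exon, against 1 with the other reading. All 227 gene identifiers were found in the annotation. Symbols come from the annotation. In 16 events the listed gene did not overlap the event's exon on the same strand, and the overlapped gene is then named too. All events lie on the 5 nuclear chromosomes.

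Genes with events were compared with 20 gene lists fixed before the data were examined, by Fisher's exact test against the 24229 genes with an annotated intron, with Benjamini-Hochberg adjustment. The plastid and mitochondrial lists matched no gene, because locus names of organelle genes are written otherwise in this annotation, so 18 lists were tested. Of the 19 genes written for chloroplast splicing, 18 were matched. Short capital names such as RING were matched in capitals only, a choice made after a first run had matched RING inside the word flowering. Overlaps between tables were set against the number for independent lists. Each retained intron that equalled an annotated intron was compared with the mean of the other introns in the gene's transcript with the most introns. The test was a within-gene permutation with 100000 resamples, two-sided, with Benjamini-Hochberg adjustment over 5 properties in every setting, and splice site scores came from position weight matrices of all annotated nuclear introns. Distances between alternative sites were tested for multiples of 3 against 1 in 3 by an exact binomial test, two-sided.

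Genes are named by a rule fixed before the data were examined. It takes members of the lists for SR proteins, the spliceosome, chloroplast splicing, embryo patterning, endosperm and seed coat, and the circadian clock. It adds the 3 events per table with the largest change of inclusion share in each direction, and genes in 3 or more tables. These ranks, and the setting with larger differences, compare uncorrected shares between events. They therefore depend on segment length and favour events with few reads. The rule gave 29 genes, and any other gene named was chosen after its values were seen. Other settings fixed before the data were examined were a stricter p-value (0.1 of the largest listed), larger differences, 1 event per gene, nuclear genes only, other backgrounds, looser intron matching and nearer sites. Others were chosen after seeing the data and are marked so in the closing section.

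The tests were tested on simulated data. Fisher's test on summed reads found 75% of 200 simulated events with a log2 odds ratio of 2 and called 3.61% of 1800 unchanged ones. The simulated reads held counting error only. Many listed events had more spread among their 3 values, so the 3.61% does not carry over to them. The within-gene test called 98% of simulated sets of 80 genes with a shift of 0.6 standard deviations and 2% of sets without one. The test of 2 sets of introns called 96% of 97-intron sets with a shift of 0.8 standard deviations and 5% without. Smaller shifts were not simulated, so a miss in these tests does not show that a difference is absent. The list test found a planted kinase list, the largest list, in 96% of draws of 227 genes in which kinase genes were drawn 3 times as often. Smaller lists and weaker enrichment were not simulated. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.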

Results

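The series asked how splicing of nuclear transcripts differs between lefko mutant and wild-type embryos, per its title, which also names chloroplast transcripts. The deposited tables listed 270 events in 227 genes, with 1 sample per genotype. There is therefore no replicate check of any difference below. Reads per event ranged from 4 to 3739 in the wild type and from 3 to 30376 in the mutant. At the 223 loci with an event, the median ratio of mutant to wild-type event reads was 0.471, so the mutant shares rest on fewer reads. The 3 values behind a share differed beyond counting error (chi-square test, p under 0.05) in 29 of the 120 wild-type events with enough reads and in 32 of 63 mutant events. In 11 of the 35 events named by the fixed rule the 3 values did not separate the genotypes: those of XTH25, AGP31, PAP85, AT4G34280, AT1G33615, HSL1, AT1G15175 and MEE5, and the 3 of AT5G65740.

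**Figure D1:**
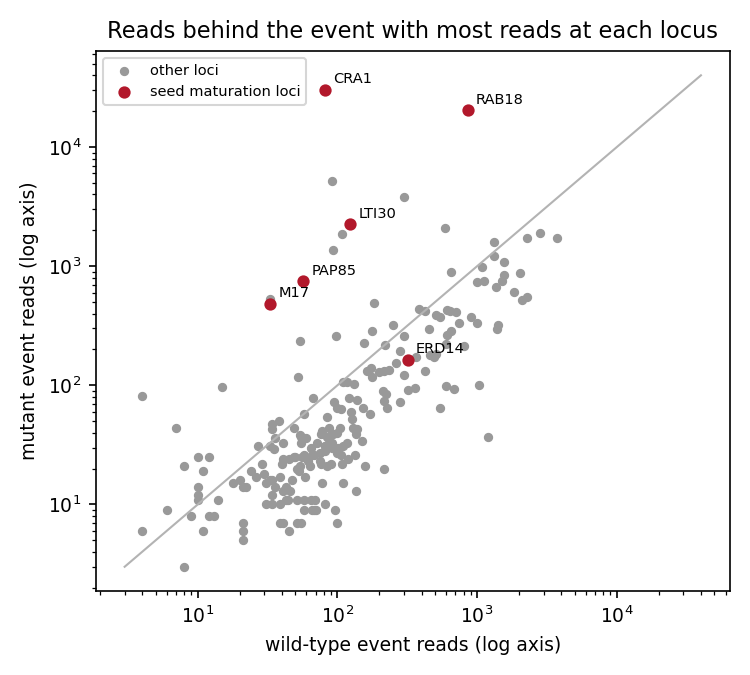
Event reads in the mutant against the wild type at 223 loci (both axes log), 1 point per locus for its event with most reads; the diagonal marks equal reads and 6 seed maturation loci, a list chosen after the events were seen, are named. CRA1, RAB18, LTI30, M17 and PAP85 lie above the diagonal and ERD14 below; the points of CRA1, PAP85 and ERD14 rest on events that join sites over 10 kb apart.

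Introns both gained and lost retention in the mutant. In the intron retention table, 64 of 115 events had a higher retained share in the mutant and 51 a lower one. SR30, which encodes a serine/arginine-rich splicing factor, kept its 604-base intron between coding exons (chromosome 1, 2943565 to 2944168) in 84.0% of wild-type reads (95% interval 79.8 to 87.6, 362 reads). In the mutant the share was 56.8% (46.3 to 67.0, 95 reads), with 39.3% to 72.7% over the 3 mutant values and 78.8% to 89.2% over the 3 wild-type values. The authors' deposited table gives this event an FDR of 0.00613. Retention of this intron would bring a stop codon into frame.

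The largest losses of retention were in AT1G72416, AT4G28790 and AT1G10810, which encode a DnaJ-domain chaperone, a bHLH DNA-binding protein and an oxidoreductase. The AT1G72416 intron (chromosome 1, 27259045 to 27259220) was retained in 13 of 13 wild-type reads and 0 of 8 mutant reads, which allows a mutant share of up to 37.5%. The AT4G28790 share was 83.3% of 12 wild-type reads and 0 of 25 mutant reads, which allows up to 12%. The AT1G10810 share was 90.9% (58.7 to 99.8) of 11 wild-type reads and 14.6% (6.1 to 27.8) of 48 mutant reads. The largest gains were in SYP73, a syntaxin, and in AT2G43700 and AT2G42640, which encode kinase-like proteins. SYP73 rose from 1 of 10 wild-type reads (0.3 to 44.5) to all 14 mutant reads (76.8 to 100). AT2G42640 had 24.4% of 45 wild-type reads and all 6 mutant reads, and AT2G43700 had 12.5% of 8 wild-type reads and all 3 mutant reads. Fisher's exact test gave p = 0.000687 and 0.0242 for the last 2, which compares the samples and not the genotypes.

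Among the 115 retention events, 54 introns lay between coding exons, 27 in the 5′ UTR and 6 in the 3′ UTR. Another 10 were in transcripts without coding sequence, and 18 equalled no annotated intron of the listed gene. Of the 54 between coding exons, 41 held a stop codon in frame, and 10 had no stop and a length that is a multiple of 3. Events with many reads, chosen after their values were seen, also went both ways. ILR1, an amidohydrolase of auxin conjugates, had 35.3% (33.7 to 36.8, 3739 reads) in the wild type and 8.65% (7.4 to 10.1) in the mutant. AT2G29210, named by the annotation for a splicing factor, had 89.7% (87.5 to 91.6) in the wild type and 99.2% (97.7 to 99.8) in the mutant.

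**Figure D2:**
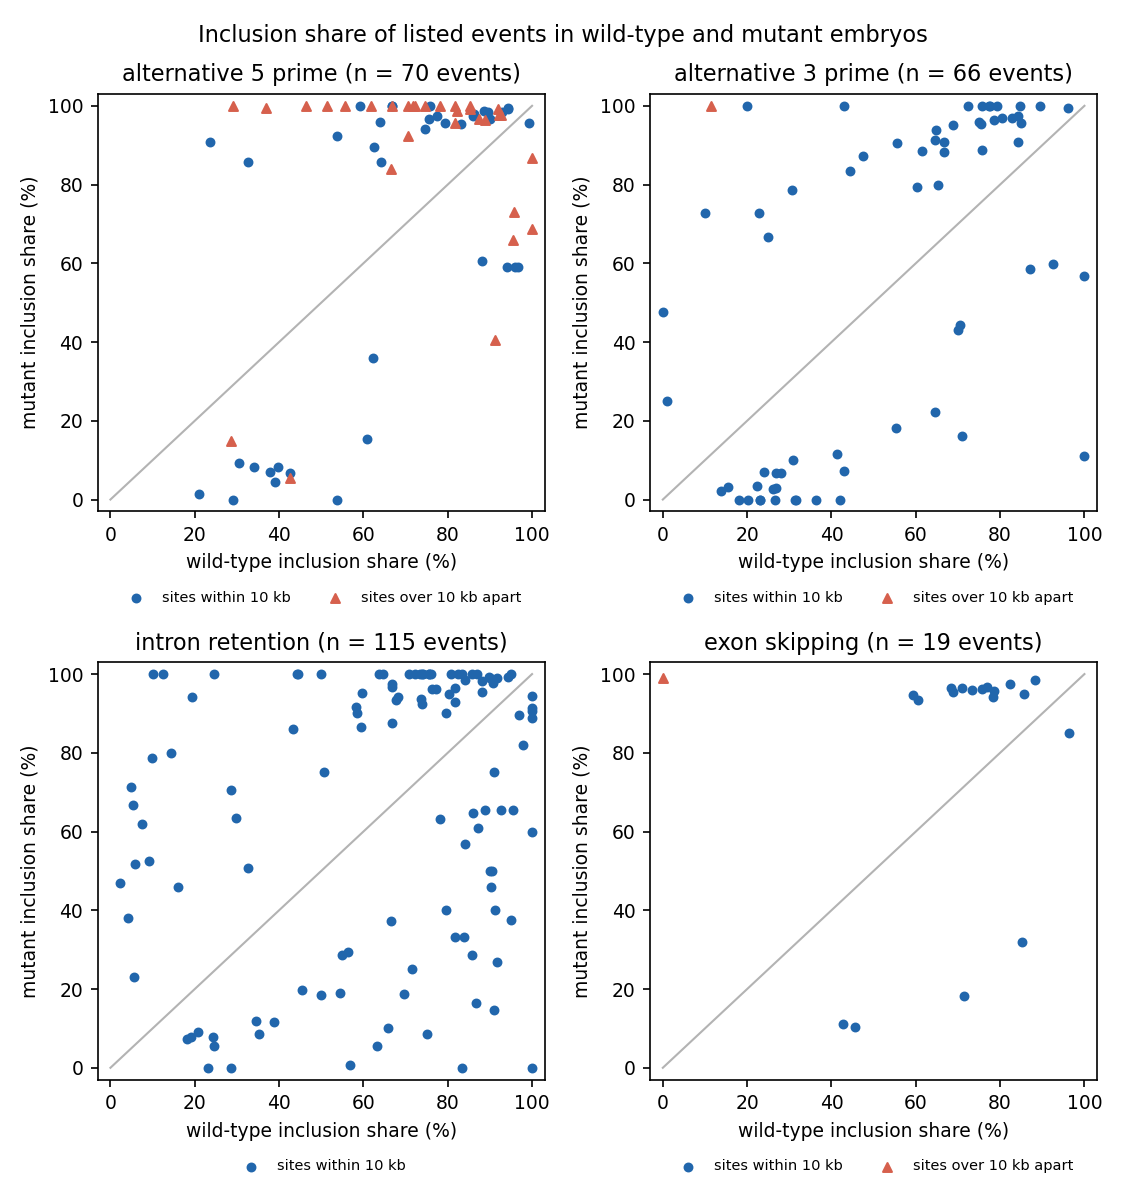
Inclusion share in the mutant against the wild type (both in %), 1 point per listed event, in 4 panels by event type; the diagonal marks equal shares and triangles mark events whose joined sites lie over 10 kb apart. Points lie above the diagonal for 64 of the 115 retention events and 14 of the 19 exon skipping events.

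In the alternative 5′ splice site table the share of the longer exon was higher in the mutant in 47 of 70 events and lower in 23. Over events with differences at or above the median of the table the split was 18 and 17, and without the 31 events that join sites over 10 kb apart it was 23 and 16. AT5G57300, a methyltransferase-family gene, used the longer exon in 23.5% (10.7 to 41.2) of 34 wild-type reads and 90.7% (77.9 to 97.4) of 43 mutant reads. TAF2, a subunit of the basal transcription machinery, went the other way, from 53.7% (37.4 to 69.3) of 41 reads to 0 of 7, which allows up to 42.9%. The kinase gene AT2G37840 had 60.9% (45.4 to 74.9) of 46 reads and 15.4% (1.9 to 45.4) of 13. Among the 3 largest changes in each direction were also XTH25, which had the largest gain, AGP31 and PAP85, whose events join sites over 10 kb apart and whose 3 values did not separate. One XTH25 event had 29.0% of 62 wild-type reads (9.76% to 100% over the 3 values) and all 185 mutant reads, while another at the same gene had 42.5% (6.10% to 100%) and 5.36%. AGP31 had 36.9% of 279 wild-type reads (7.75% to 100%) and 99.5% of 196 mutant reads. PAP85 had 91.2% of 57 wild-type reads (37.5% to 100%) and 40.5% of 754 mutant reads (19.0% to 62.9%).

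Of the 66 alternative 3′ splice site events, 37 were higher in the mutant and 29 lower. With the stricter p-value the split was 15 and 17. RPH1, a gene named for resistance to Phytophthora, used the site 3 bases upstream in 70.9% (57.1 to 82.4) of 55 wild-type reads and 16.2% (6.2 to 32.0) of 37 mutant reads. AT1G62610, an NAD(P)-binding protein gene, rested on 2 of 10 wild-type reads (2.5 to 55.6) and all 25 mutant reads, and AT5G03406 on 1 of 10 and 8 of 11. AT1G33615, a non-coding RNA gene, had 6 of 6 wild-type reads and 11.1% of 9 mutant reads. AT3G14880 had 4 of 4 wild-type reads against 56.8% (45.3 to 67.8) of 81 mutant reads, a difference that Fisher's exact test did not call (p = 0.140). The event listed under AT4G34280 overlaps no annotated gene and joins sites over 10 kb apart, with 11.4% of 132 wild-type reads (6.56% to 100% over the 3 values) and all mutant reads (96.5 to 100).

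Exons were included more often in the mutant in 14 of the 19 exon skipping events, and in 6 of the 10 with differences at or above the median of the table. KAT5, a 3-keto-acyl-CoA thiolase of fatty acid breakdown, included an exon (chromosome 5, 19816923 to 19817029) in 59.3% (56.5 to 62.0) of 1247 wild-type reads and 94.6% (91.5 to 96.8) of 314 mutant reads. The 3 wild-type values ran from 57.4% to 60.6% and the 3 mutant values from 93.7% to 95.2%. AT1G45248, a histone methyltransferase-related gene, went from 60.5% (43.4 to 76.0) of 38 reads to 93.3% (68.1 to 99.8) of 15. Lower inclusion was seen for HSL1, a relative of the seed gene repressor HSI2, at 71.4% of 14 and 18.2% of 11 reads. The event listed under the non-coding gene AT3G00650, whose exon overlaps no annotated gene on its strand, went from 85.3% to 31.9%. The non-coding gene AT1G15175 went from 45.6% to 10.3%. MEE5, the gene of the spliceosome GTPase listed as GFA1, had 42.6% (30.7 to 55.2) of 68 wild-type reads and 11.1% (0.3 to 48.2) of 9 mutant reads. The authors' deposited table gives the MEE5 event an FDR of 0.0285, while Fisher's exact test on the summed reads gave p = 0.0824. The event listed under MYA2 ends in the cruciferin gene CRA1 over 10 kb away, with 0 of 81 wild-type reads, which allows up to 3.70%, and 99.0% of 30376 mutant reads.

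The listed events were a small part of those the authors tested, which came to 2002 alternative 5′, 2788 alternative 3′, 5174 retention and 3187 skipping events. The listed shares were 3.50%, 2.37%, 2.22% and 0.596%. On summed reads, 228 of the 270 events had a Fisher's exact p under 0.05 and 42 did not. The 3 values of one genotype all lay above or below those of the other in 193 events (71.5%), where chance alone gives 10% of events, but the events were selected for a difference.

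No gene list fixed before the data were examined passed the test among genes with events. The kinase list, which takes genes by words in their names or synonyms, came closest. It had 21 genes where 11.6 were expected (fold 1.81, Fisher's exact p = 0.00893, adjusted p = 0.161). Their events went both ways, 12 higher and 13 lower in the mutant. All events of AT4G30820, named for a kinase assembly factor and not a kinase, are among the 12 although they share skipping reads. Genes whose names or synonyms mention splicing, small nuclear ribonucleoproteins or serine/arginine-rich proteins numbered 4 where 1.13 were expected (Fisher's exact test, adjusted p = 0.245): SR30, AT2G29210, AT3G04160 and AT1G67850, the last only by the word trans-splicing in its name. The SR protein and spliceosome lists had 1 gene each, SR30 and MEE5. No gene on the lists for chloroplast splicing, embryo patterning, endosperm and seed coat, the circadian clock, photosynthesis or tRNA synthetases had an event. Only 0.0743 to 0.836 genes were expected on each of these lists, so the 0 says little about these classes. The lists for ribosomal proteins (3 genes), RNA-binding proteins (4), chloroplast-named (2) and embryo-defective genes (3: EMB2654, MEE22 and THO2) did not pass either. Nor did those for chaperones (2), transcription factors (11), ubiquitin-related (5) and pentatricopeptide proteins (1), with adjusted p from 0.798 to 1 over these lists (Fisher's exact test). They take genes by words in annotated names, so the counts are not those of whole classes. The ribosomal list took in MEE5, and the chaperone list left out HSP70T-2, which had an event. The expressed genes are not known from these tables, so the background includes genes that could not have had an event.

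Some genes were listed in more than 1 table. AT3G27990, a non-coding RNA gene, AT4G30820, for a CDK-activating kinase assembly factor, and AT5G65740, for a zinc ion binding protein, were in 3 tables each. Within each gene the 3 events had the same skipping counts in each genotype, so they are not separate evidence and 1 event per gene is given. AT3G27990 had 88.8% (86.2 to 91.1) retention of a 3480-base intron in the wild type and 65.6% (55.0 to 75.1) in the mutant, with 76 and 32 skipping reads. AT4G30820 retained an intron in the 5′ UTR in 63.6% of 22 wild-type reads and in all 14 mutant reads, with 8 and 0 skipping reads. AT5G65740 had 74.0% of 50 reads and 92.3% of 13 for retention, which Fisher's exact test did not call (p = 0.265). Alternative 5′ and retention events shared 8 genes against 0.243 expected, alternative 3′ and retention 5 against 0.288, alternative 5′ and 3′ 3 against 0.143, and alternative 5′ and skipping 3 against 0.0312. Exon skipping shared 0 genes with retention or alternative 3′ events. Expected numbers assume independent lists, whereas transcripts with many reads enter every table more easily, and 1 region can be listed in several.

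Listed retained introns were richer in G and C than the other introns of their genes. Those others were annotated introns and not the retention events the authors tested. A trait of introns that can be retained at all therefore cannot be told apart from an effect of the mutant. Over 97 introns in 94 genes, the median difference was 1.32 percentage points, and 62 introns lay above the mean of the others (within-gene permutation p = 0.00758, adjusted p = 0.0379 over 5 properties). Against the median of the other introns the difference was 1.25 points and no longer passed the permutation test (adjusted p = 0.0950). Their length (median difference -9.67 bases, adjusted p = 0.137), 5′ splice site score (-0.24 bits, 0.317), 3′ splice site score (-0.72 bits, 0.137) and position (6.40 points of gene length, 0.317) did not pass the same permutation test. In a split chosen after seeing the data, introns more retained in the mutant sat toward the 5′ end of their genes and those less retained toward the 3′ end. The medians relative to the other introns were -23.2 and 21.4 points of gene length, a difference of -44.6 points over 53 and 44 introns (permutation p = 0.00240, adjusted p = 0.0120). Over events with Fisher's exact p under 0.05 the difference was -44.4 points and no longer passed (adjusted p = 0.0692). Most of the 27 introns in the 5′ UTR were more retained in the mutant. The split was not repeated without them, so position cannot be told apart from place in the transcript. The same comparison of more with less retained introns gave no detectable difference in GC (-0.164 points, permutation, adjusted p = 0.898).

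**Figure D3:**
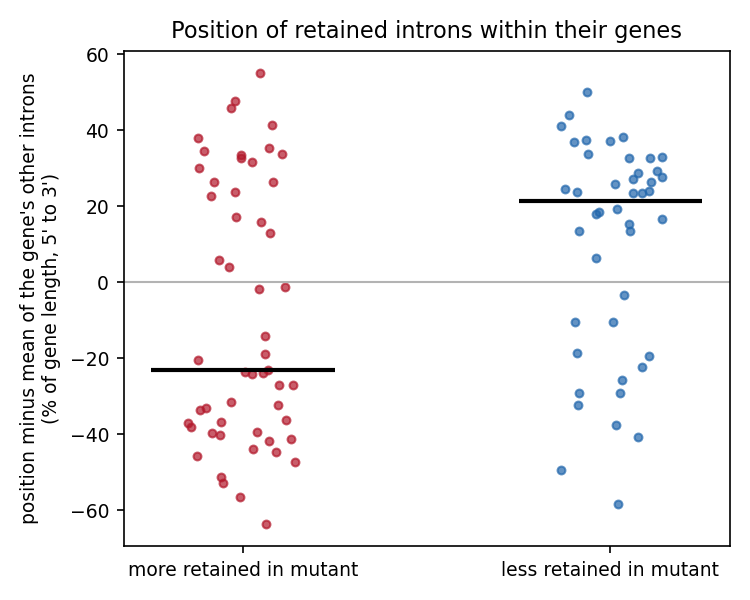
Position of each retained intron minus the mean position of the other introns of its gene, in % of gene length from 5′ to 3′, for 53 introns more retained and 44 less retained in the mutant; black bars are medians. The medians lie at -23.2 and 21.4.

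Alternative splice sites showed no detectable preference for the reading frame. The median distance between paired sites was 10.5 bases for 3′ and 48.5 bases for 5′ events. At 5′ sites it was 189 bases (4 to 2681) in the 39 events within 10 kb and 23 bases (3 to 89) in the 31 that join sites over 10 kb apart. Multiples of 3 made up 32.9% (22.1 to 45.1) of 70 distances at 5′ sites (exact binomial p = 1) and 36.4% (24.9 to 49.1) of 66 at 3′ sites (p = 0.603), against 33.3% by chance. Both alternative 3′ sites ended in AG in all 66 events. At alternative 5′ sites, 42 of 70 events had GT at both sites. Of the 31 that join sites over 10 kb apart, 4 did, against 38 of the other 39.

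**Figure D4:**
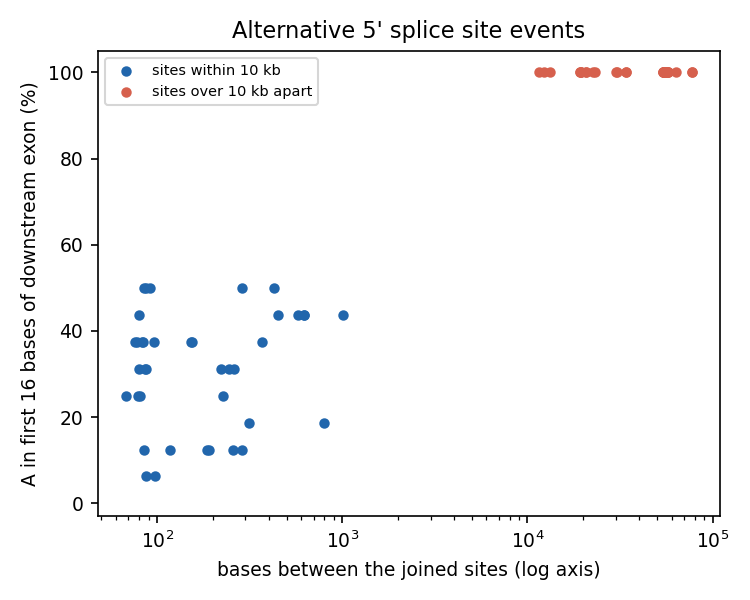
Share of A in the first 16 bases of the downstream exon (%) against the distance between the joined sites (bases, log axis), 1 point per alternative 5′ event. The 31 events with sites over 10 kb apart all lie at 100%, and the median of the other 39 is 31.2%.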

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

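Of the tests in this part, 5 of the 7 were chosen only after the result was seen; the test of A-rich ends and the test of agreement between the 3 values were not. The reads behind the events, summed over both kinds, enter no splicing comparison above and were given there as depth. Of the 223 loci, 11 had over 10 times as many event reads in the mutant. On a list of genes named for seed maturation, chosen after the events were seen and so not tested for enrichment, 5 of 6 loci were among them, and the median ratio of mutant to wild type was 16.4. The other 6 of the 11 were not on the list: AT1G14950 (56.9), AT3G14880 (20.3, on 4 wild-type reads), XTH25 (17.3), AT2G48130 (16.0), AT3G19920 (14.8) and FOLB3 (12.8). The ratios of AT1G14950 and XTH25 rest on events that join sites over 10 kb apart. Another XTH25 event had a smaller excess, with 62 wild-type and 185 mutant reads. CRA1, a cruciferin storage protein gene, had 81 wild-type and 30376 mutant reads in 1 event and ratios of 15.1 and 14.5 in its other 2, and all 3 join sites over 10 kb apart. The dehydrin genes RAB18 and LTI30 had ratios of 23.7 (95% counting interval 22.1 to 25.4) and 18.2 (15.1 to 21.9). The other RAB18 event, which joins sites over 10 kb apart, had a ratio of 45.8. M17, a late embryogenesis abundant protein gene, had 14.7 (10.3 to 21.6), and the cupin gene PAP85 13.2 (10.1 to 17.6). The dehydrin gene ERD14 did not share this, at 0.514 (0.423 to 0.623), close to the median of all loci. In settings chosen after seeing the data, without events that join sites over 10 kb apart 3 loci of the list remained, with a median of 18.2. None of the retained introns listed at these loci, RAB18, LTI30 and M17, equalled an annotated intron of the gene. With the event of fewest reads at each of the 6 loci the median was 14.2.

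The median ratio over all 223 loci was 0.471, which argues against deeper sequencing of the mutant. A later stage of the mutant embryos when collected may account for the 16.4-fold median and cannot be told apart from an effect of the genotype, because each genotype is 1 sample. An effect of the mutation on these genes stays open and was not tested.

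Of the 70 alternative 5′ events, 31 join sites 11558 to 77340 bases apart, and all 31 lie on the minus strand. Of the 31 pairs, 0% were annotated introns or had the downstream exon inside the gene. The pairs of all 39 other events were annotated introns. Choosing sites over 10 kb apart makes either outcome unlikely from the start, so this test cannot decide on long introns without annotation. GT stood at both sites in 4 of the 31 events, against 38 of the other 39. A candidate explanation is poly(A) tails aligned to a distant A-rich stretch, since the first 16 bases of the downstream exon were 100% A at the median, against 31.2% in the other events. The median event reads were 10.2 times those of other alternative 5′ events, as misplaced reads of abundant transcripts would give. No explanation by genotype was tested.

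In 15.6% of the listed events, 42 of 270, the summed reads gave a Fisher's exact p of 0.05 or more, although the authors' FDR was under their threshold. Their median mutant depth was 12.5 reads, against 63 in the others. Close agreement of the 3 values would separate them in most of these events, and it did so in 33.3%, which argues against that explanation. The authors' test may give small values at few reads, but Fisher's exact test also misses real changes there, and the 2 cannot be told apart. In the simulation with a log2 odds ratio of 2 it found 75% of events, and 93.9% of those with 30 reads or more in each genotype. The caller is not named in the sources used here, and no biological explanation was tested.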

How the results depend on the processing

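Settings chosen only after seeing the data were those on separated shares, Fisher's exact test, 10 reads, sites over 10 kb apart, introns more or less retained, genes by coordinates and letter case in list names; the others were fixed before the data were examined. With the stricter p-value, alternative 5′ events numbered 25 higher and 18 lower in the mutant, alternative 3′ events 15 and 17, retention events 41 and 32, and skipping events 10 and 1; the alternative 3′ split thus passed from 56.1% to 46.9% higher. With only differences at or above each table's median, the numbers were 18 and 17 for alternative 5′, 17 and 16 for alternative 3′, 30 and 28 for retention, and 6 and 4 for skipping; alternative 5′ events thus passed from 67.1% to 51.4% higher. Fewer events enter both settings by construction. Events whose 3 shares separated numbered 23 and 16 for alternative 5′ and 11 and 2 for skipping. Without sites over 10 kb apart, alternative 5′ events numbered 23 and 16. All other counts moved by at most 1.5 times, and the nuclear-only setting moved none. No gene list passed under any of 7 other settings, with a lowest adjusted p of 0.0768 (Fisher's exact test). That value belongs to the list of splicing-related names with the stricter p-value (fold 6.11), where the kinase list had 0.224.

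Overlap ratios between tables stayed within their counting intervals. By permutation p adjusted over 5 properties, the GC difference of retained introns passed with looser intron matching and with introns of any transcript and missed against the median of the other introns (1.25 points, adjusted p = 0.0950). Its adjusted p ran from 0.0122 to 0.110 over 5 settings. Length passed with looser matching (-6.86 bases) and with any transcript (-9.67 bases) and was 3 bases against the median, where it did not pass (permutation, adjusted p = 0.467). The 3′ site score passed with looser matching (-0.847 bits). Among introns more retained in the mutant, length reversed to 10.6 bases and position to -23.2 points, and both passed, as did the 3′ score at -1.13 bits, while GC missed at 1.27 points. Among those less retained, position passed at 21.4 points and GC missed at 1.44 points; fewer introns enter both sets. The difference between the sets in position was -44.4 points and missed (adjusted p = 0.0692) over events called by Fisher's exact test, where fewer introns enter. The difference between the sets in length was 44.2 bases in the main setting and missed (permutation, adjusted p = 0.0684). Over events with 10 reads or more in each genotype it passed at 72.1 bases. In the other cases the cause was not tested. The share of multiples of 3 passed the test in none of its 3 other settings. No paired analysis was possible because each genotype has 1 sample. Mutant depth, a median of 43.5 reads per event, limits the size of a difference that can be seen.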

Other observations

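Other genes outside the naming rule, chosen after their values were seen, are given here; their depths differ. GEX1, known from gametes and embryos, had 3 retained introns, and each fell in the mutant: from 75.0% (61.1 to 86.0) to 8.55% (4.2 to 15.2), from 91.7% to 26.9% and from 56.8% to 0.820%. ORP4C, an oxysterol-binding protein relative, had 83.8% (80.8 to 86.6) retention in the wild type and 33.3% (30.2 to 36.4) in the mutant. MYB60, a transcription factor of guard cells, had 24.3% of 1835 reads and 7.70% of 610. EMB2654, from the embryo-defective list, had 56.3% (52.6 to 59.9) and 29.4% (24.6 to 34.6).

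In the other direction, FOLB3, of folate synthesis, included an exon in 68.8% (63.2 to 74.0) of 298 wild-type reads and 95.5% (94.8 to 96.2) of 3814 mutant reads. HTA11, a histone H2A.Z gene, had 78.2% (75.9 to 80.3) and 94.2% (90.9 to 96.6). MEE22, also on the embryo-defective list, retained an intron in 73.3% (61.9 to 82.9) of 75 wild-type reads and in all 23 mutant reads. STK, a MADS-box gene of ovules and seeds, had 64.0% (53.2 to 73.9) of 89 wild-type reads and 95.8% (78.9 to 99.9) of 24 mutant reads in 1 alternative 5′ event. Its other 2 events were higher in the mutant too but share the same 32 wild-type skipping reads and 1 mutant skipping read, so they are not separate evidence.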
